A study of Abies pinsapo with 24 samples.

How the data were processed

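RNA-seq was run on needles and roots of Abies pinsapo (Spanish fir) from Yunquera, the lower site, and Ronda, the upper site, in autumn and in spring. The labels number 3 individuals at each site, and the number was taken to name the tree: trees 1 to 3 stood at Yunquera and trees 4 to 6 at Ronda. The design thus had 8 groups of 3 libraries. The protocol of the samples gives 6 independent trees, while the series description gives a larger number of randomly selected individuals on each occasion, and neither says whether libraries were pooled or whether a number means the same tree in both organs and seasons. Every value per tree or with the tree as a block takes it to do so. The on/off calls that bear on this reading are in the report: 20 libraries shared at least 92.8% with their own tree. Per the labels' protocols, roots were extracted with a kit and needles by another method, so organ and extraction method cannot be separated. The protocols name directional and non-directional libraries without saying which sample received which, and season coincides with the calendar year of harvest.

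The deposited table holds raw read counts per feature for the 24 libraries, per the labels and the file header. CASAVA, HISAT2 and featureCounts are named in the submitters' processing notes; their versions and settings and the genome build are not given in the sources used here. The table has 51046 features on 39760 reference sequences, with a best protein hit in another species for 33405 of them, most often Arabidopsis thaliana (17688 features). Gene symbols and names in the text are those best hits, not names established in fir. Features with a gene model are given in short form: Gene_5437 stands for the feature that the table also places on reference sequence ap_4165, and every such feature named here starts at position 1 of its own sequence. The 4528 features with no gene model are given by their best hit, reference sequence, start and end in bases, as the file counts them. No genome was used here. Of the 168 features that the naming rule took, 1 overlapped another feature, on the other strand. Members of families with near-identical copies, such as early light-induced proteins, expansins, chalcone synthases and WAT1-related transporters, can share reads, and their separate values are uncertain for that reason.

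Every library column matched the description of 1 sample. Total counts ran from 13355301 to 27427263 per library. A count of 0 allows up to 3 counts, which is 0.109 to 0.225 normalised read counts (CPM, counts scaled to equal library totals) in a single library; where a group was at 0, its bound was 3 counts over the summed totals of that group. Intervals and floors cover counting error only. The replicates of a group all differed from each other by more than sampling noise in a chi-square comparison of their counts.

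Counts were tested with edgeR 4.0.16 in R 4.3.3: trimmed-mean normalization factors, the filterByExpr filter (count minimum 10, total minimum 15), quasi-likelihood fits on the group means and Benjamini-Hochberg adjustment over the features tested, with a threshold of 0.05. Season and site were tested in the 12 libraries of an organ and organ and season by organ in all 24 libraries, 15 comparisons in all. Log2 fold changes are spring minus autumn, Ronda minus Yunquera and needles minus roots, and are given with the standard error (SE). In comparisons over both sites they are the mean of the values at the 2 sites, on the log2 scale. Group levels are normalised CPM as mean ± standard deviation (SD). Each fit shares its estimate of spread over its groups. These tests, the lists, the naming rule and the alternatives not named below as added were set before the data were examined.

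The text names genes by a fixed rule. Candidates passed the adjusted threshold with an absolute log2 fold change of at least 1 and a mean of at least 5 CPM in the higher group, and moved the same way in every tree or, for site, had groups that did not overlap. For season in each organ and organ in spring, the rule took at most 20 list members by adjusted p, then the 5 largest rises and 5 largest falls. Other comparisons took at most 5 list members and the 2 largest rises and 2 largest falls. For interactions only the adjusted p and the level counted. The rule was repeated without 2 libraries whose organ transcripts went against their label; that repeat, like every value without those libraries, was added after the data were seen. The text names some of these genes. A few others were chosen after their values were seen, and the text says so.

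Features were assigned to 25 gene lists by fixed patterns in the best-hit name and protein domains; a list was used when at least 5 members were tested, and a feature can be in several. The lists were light harvesting and photosystems; carbon fixation; photoprotection and carotenoids; heat shock proteins and chaperones; dehydrins and late embryogenesis abundant (LEA) proteins; abscisic acid; phenylpropanoids and lignin; flavonoids; terpenoids; cell wall growth; cell cycle and DNA replication; circadian clock and light signalling; flowering and phase change; oxidative stress; nitrogen and amino acid transport; aquaporins; raffinose, starch and sucrose; pathogenesis-related and defence; jasmonate and ethylene; auxin, gibberellin and cytokinin; ribosomal proteins; cuticle, wax and suberin; and, as markers of other organisms or tissues, fungal or animal sequence, bacterial sequence, and pollen and reproductive tissue. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and with fry, all adjusted over lists and comparisons. Camera compares a list with the other genes. Fry tests whether a list's genes move, on balance, 1 way and compares them with no other genes.

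Alternatives were relative log expression (RLE) size factors, DESeq2 1.42.0, no filter, a stricter filter (5 CPM in 3 libraries), a minimum log2 fold change of 1, only the 6 libraries compared, each library left out in turn, and the tree as a replicate block (for site, as a random term in limma-voom). Fits without the 2 libraries, with and without the block or by DESeq2, and without the needle libraries of tree 1 were added after the data were seen. Samples were never regrouped by their values. The pairing of libraries rests on the numbers in the labels. Correlations of deviations from the group means between autumn and spring libraries of a tree, without the 2 libraries, ran from -0.292 to 0.546 in needles (above 0.1 in 4 of 5 trees) and from 0.168 to 0.365 in roots (5 of 5 trees).

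The test was run on simulated counts with 200 changed genes. Levels and spread for the simulation came from the fits of the 24 libraries as labelled. The shares called apply to those fits and were not obtained for the fits without the 2 libraries. For season in needles over 18948 simulated genes tested, it called 8.96% of 2-fold, 46.3% of 4-fold and 65.2% of 8-fold changes, and for season in roots over 17387 genes it called 50% of 8-fold changes. For the season by site interaction over 17449 simulated genes in roots, it called 0 of 66 genes changed 8-fold. Every changed gene called had the right direction. To compare trees, 66 features were used that were on (above 4 CPM) in at least 4 libraries and off (below 0.5 CPM) in at least 4, with at most 2 libraries in between and shares of libraries on that differed by less than 0.35 between organs and between seasons; a match was a mean of 90% equal calls. Needle-specific features passed the adjusted threshold for organ in autumn, without the 2 libraries, with a log2 fold change of at least 5. Plots were drawn with matplotlib 3.10.9.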

Results

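RNA was sequenced from needles and roots of adult Abies pinsapo (Spanish fir) trees 30 to 50 years old in Sierra de las Nieves. Trees at Yunquera stood at 1100 to 1200 m, the lower limit of the forest, and trees at Ronda at 1700 to 1800 m, the upper limit. Harvests were in September 2022 (autumn) and May 2023 (spring), with 3 numbered individuals per site, which gave 8 groups of 3 libraries and 24 libraries in all. Total counts per library ran from 13355301 to 27427263. Of the 51046 features in the count table, 22390 had no count in any library.

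Photosynthesis transcripts separated needles from roots in 22 of the 24 libraries. Members of the light harvesting and photosystem list took 3.00 to 5.64% of the counts in 11 needle libraries and 0.0412 to 0.128% in 11 root libraries. Carbon fixation members took 1.36 to 4.12% and 0.0860 to 0.145%. The library labelled spring needles of Ronda, replicate 3 (tree 6), had 0.0370% in the photosystem list (95% Wilson interval 0.0361 to 0.0379) and 0.0885% in carbon fixation (0.0871 to 0.0899). The first was below the range of the root libraries and the second within it. The library labelled spring roots of Ronda, replicate 2 (tree 5), had 3.28% (3.27 to 3.29) and 2.38% (2.38 to 2.39), both within the range of needles. Features that are on in some trees and off in others gave each library a second identity. Shares are over those of the 66 features called on or off in both libraries. A share with a tree is a mean over its libraries, leaving out the 2 Ronda libraries above, the needles of tree 1 and the library itself. The library labelled needles of tree 6 shared 91.5% of its on/off calls with tree 5 and 62.3% with tree 6. The library labelled roots of tree 5 shared 92.3% with tree 6 and 64.3% with tree 5. The 20 other libraries outside the needles of tree 1 shared at least 92.8% with their own tree and at most 75.0% with another. Both needle libraries of tree 1 stood apart: the autumn library shared 68.7% and the spring library 67.2% with the roots of tree 1, and 61.7% with each other. Counts of genes are given for all 24 libraries as labelled and then without the 2 Ronda libraries, while gene and list values come from the 22 remaining libraries unless said otherwise.

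**Figure D1:**
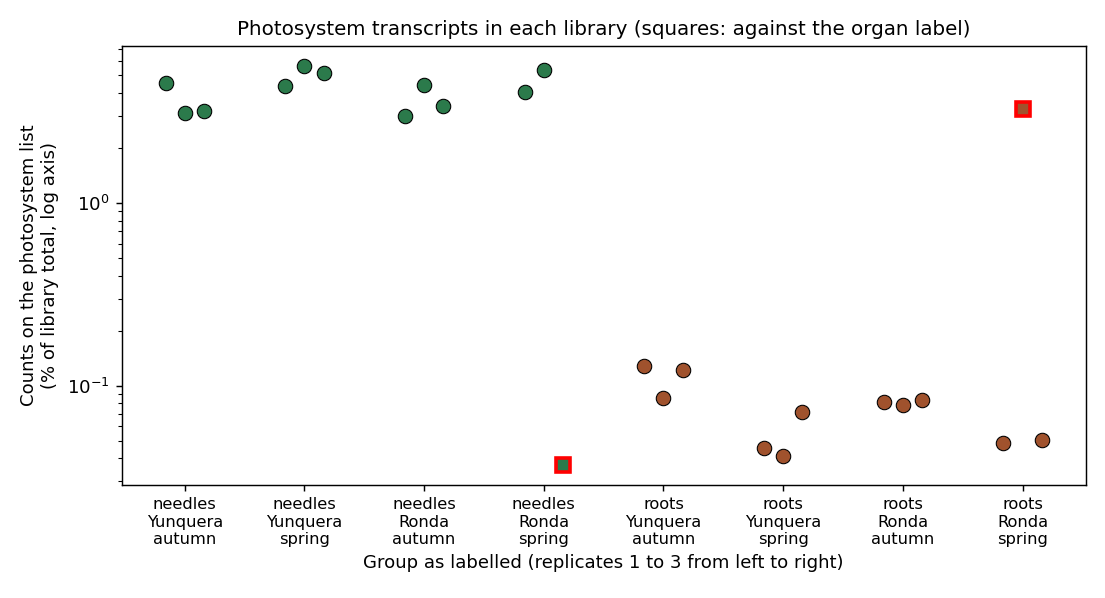
Share of counts (percent of the library total, y axis) in the light harvesting and photosystem list for each of the 24 libraries by group (x axis), with the 2 libraries that go against their organ label as red squares. The library labelled spring needles of Ronda, replicate 3, sits at 0.0370% and the library labelled spring roots of Ronda, replicate 2, at 3.28%.

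**Figure D2:**
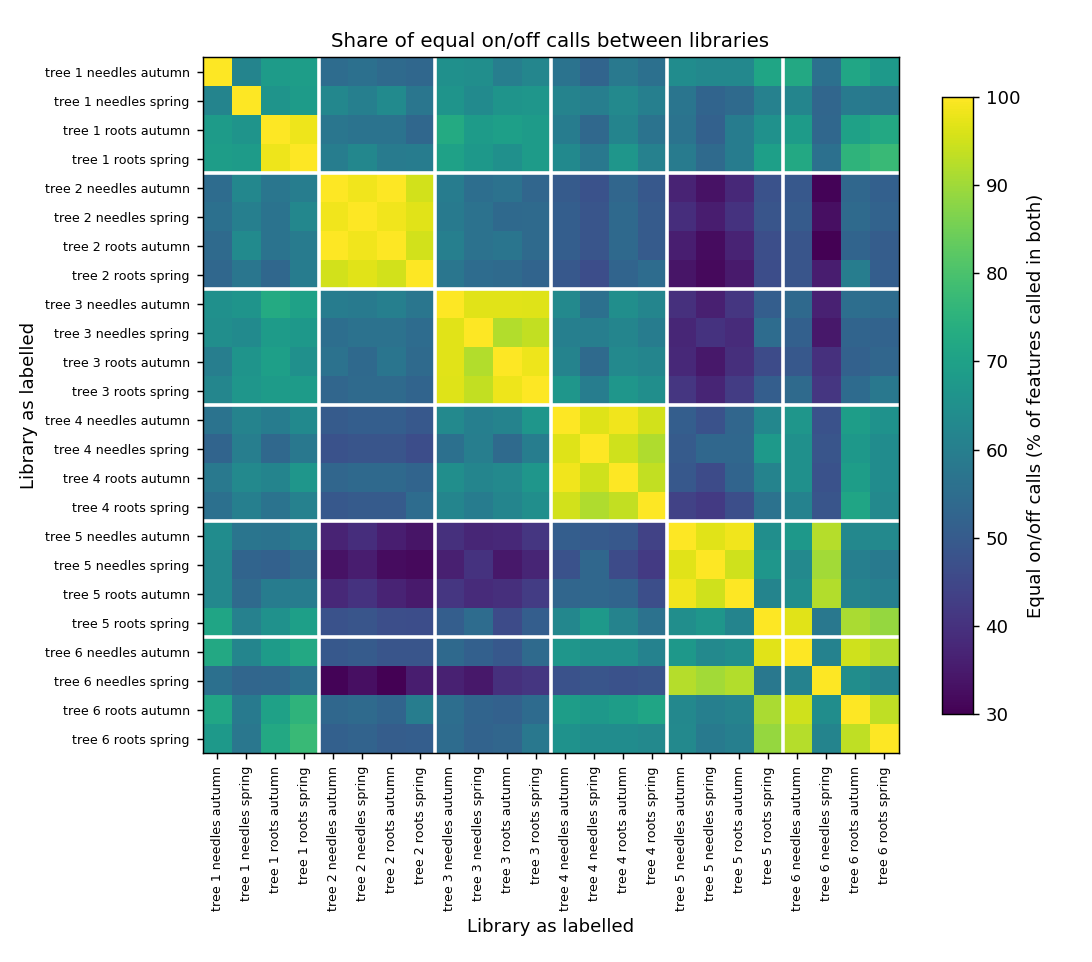
Percent of equal on/off calls between 2 libraries, for the 24 libraries on both axes, ordered by tree, with brighter colours for higher shares. Each percent is over those of the 66 features called on or off in both libraries. The library labelled needles of tree 6 in spring shares a mean of 91.5% with the libraries of tree 5, and the library labelled roots of tree 5 in spring 92.3% with those of tree 6. Both means leave out these 2 libraries, which share 58.1% with each other.

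The season comparison in needles asked how transcripts differed between the May and September harvests. Values in brackets after a gene are its log2 fold change ± SE. For both sites together that is the mean of the changes at the 2 sites, which can differ from the ratio of the mean levels. An expansin, PCNA and RBCS were among the named genes that rose in spring needles, and the dehydrins Gene_5437 and Gene_3530 among those that fell. The expansin EXPB16 (Gene_4153), a wall-loosening protein, rose from 2.60 ± 1.44 CPM in autumn (SD, n = 6) to 43.5 ± 28.9 CPM in spring (n = 5). Its log2 fold change was 4.10 ± 0.53. PCNA (Gene_8877), the sliding clamp of DNA replication, rose from 0.633 ± 0.751 to 9.44 ± 7.89 CPM (6.57 ± 0.58). RBCS (ap_2297, 1 to 932), the small subunit of Rubisco, rose from 1491 ± 452 to 11018 ± 2595 CPM (2.87 ± 0.23). In the 24 libraries as labelled it missed the threshold (2.59, adjusted p = 0.141 by edgeR). Dehydrins are hydrophilic proteins of drying or cold tissue. Gene_5437 fell from 1831 ± 802 to 84.6 ± 52.4 CPM (-4.88 ± 0.46), and Gene_3530 from 402 ± 204 to 0.853 ± 0.344 CPM (-8.80 ± 0.49).

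Among further wall genes named by the rule, PME68 (Gene_13342, a pectinesterase; log2 fold change = 4.24 ± 0.55), XTH8 (Gene_27417, 3.35 ± 0.39) and EXPA8 (Gene_10716, 5.40 ± 0.52) rose, while XTH9 (Gene_18492, -5.18 ± 0.78) fell. The cyclin-dependent kinase inhibitor KRP5 (Gene_12429, 2.51 ± 0.22) and histone H3.3 (Gene_1, 1.24 ± 0.13) rose. So did the water channels PIP2-8 (Gene_3516, 1.31 ± 0.14) and PIP1.4 (Gene_2961, 1.31 ± 0.15), and CYP707A4 (Gene_40730, 1.93 ± 0.23), an enzyme of abscisic acid breakdown. The starch-degrading amylases AMY3 (ap_33391, 1 to 1827, -2.33 ± 0.18) and BAM1 (ap_31763, 1 to 2851, -2.76 ± 0.30) fell. So did LEA14-A (Gene_4579, -5.17 ± 0.63), the clock gene ELF3 (Gene_31887, -1.71 ± 0.16), the transcription repressor RAV2 (Gene_52918, -6.30 ± 0.45) and the glutathione transferase GSTU18 (Gene_22298, -1.49 ± 0.13). The raffinose-forming galactosyltransferase RFS (ap_60466, 6 to 1730, 1.80 ± 0.21) and the small heat shock protein HSP17.7 (Gene_7362, 2.70 ± 0.26) rose. Adjusted p for the genes of both paragraphs on needles ran from 6.15e-05 to 0.00327 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each moved the same way in all 5 trees with both libraries, which the naming rule required. Tree 1, whose needle libraries shared 61.7% of on/off calls, is 1 of the 5.

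Cell wall growth and the cell cycle were the lists with the most members up. Of 159 cell wall members tested, 55 rose and 10 fell (72 and 13 adjusted over the list alone), with a median log2 fold change of 1.16. Camera gave adjusted p = 9.38e-08, and adjusted p = 0.68 with an estimated correlation. Of 204 cell cycle members, 70 rose and 3 fell (86 and 4 adjusted over the list alone, median 0.64), with camera adjusted p = 2.27e-10 and adjusted p = 0.695 with an estimated correlation. Fry gave adjusted p = 0.0226 and 0.0276 for these lists. With the tree as a block, 16 cell wall members rose and 4 fell, 25 cell cycle members rose and 3 fell, and the fry values were 0.138 and 0.125. Of 29 aquaporins, 6 rose and 2 fell (7 and 2 adjusted over the list alone, median 0.19, camera adjusted p = 0.0261, adjusted p = 0.704 with an estimated correlation, 0.0677 with the block, and 0.0579 as labelled). Of 61 terpenoid members, 6 rose and 1 fell, equal to the numbers adjusted over the list alone (median 0.81, camera adjusted p = 0.0484, adjusted p = 0.864 with an estimated correlation, 0.0563 with RLE size factors, and 0.402 as labelled). Of 79 photosystem members, 7 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.33 and camera adjusted p = 0.0871. The fry value was 0.365, and 0.0452 with the block. Of 33 dehydrin and LEA members, 9 rose and 6 fell (9 and 7 adjusted over the list alone): the median was 0.62 and the mean 0.37, while camera pointed down with adjusted p = 0.522.

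The remaining lists had calls on both sides or few calls, and camera passed none of them (adjusted p from 0.0809 to 0.999). Fry, which asks whether members move on balance 1 way, passed oxidative stress and jasmonate and ethylene. Oxidative stress had 51 of 274 higher and 20 lower (56 and 25 adjusted over the list alone, fry adjusted p = 0.0312, and 0.061 with the block). Jasmonate and ethylene had 17 of 143 higher and 13 lower (19 and 13 adjusted over the list alone, fry adjusted p = 0.025). Phenylpropanoids and lignin had 13 of 73 higher and 4 lower (18 and 4 adjusted over the list alone). Flavonoids had 12 of 113 higher and 5 lower (12 and 5 adjusted over the list alone), and cuticle, wax and suberin 6 of 37 and 1 (7 and 1). Nitrogen and amino acid transport had 17 of 91 and 6 (20 and 7), and raffinose, starch and sucrose 14 of 83 and 9 (16 and 9). Heat shock proteins had 19 of 212 higher and 17 lower (19 and 19 adjusted over the list alone), and abscisic acid 6 of 70 and 10 (8 and 10). Auxin, gibberellin and cytokinin had 12 of 110 and 11 (15 and 13), and defence 24 of 257 and 16 (24 and 16). Photoprotection had 2 of 34 higher and 0 lower (0 and 0 adjusted over the list alone), and carbon fixation 1 of 23 and 2 (1 and 2). The circadian clock had 2 of 21 and 1 (2 and 2), flowering 0 of 33 and 1 (0 and 0) and ribosomal proteins 5 of 432 and 13 (0 and 0). Among marker lists, fungal or animal sequence had 8 of 532 higher and 15 lower (4 and 5 adjusted over the list alone). Bacterial sequence had 9 of 154 and 7 (8 and 6) and pollen and reproductive tissue 8 of 47 and 5 (10 and 6). In 5 of these lists the camera direction was down while the mean was above 0: abscisic acid (mean 0.07), circadian clock (0.15), raffinose, starch and sucrose (0.23), defence (0.15) and ribosomal proteins (0.20).

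**Figure D3:**
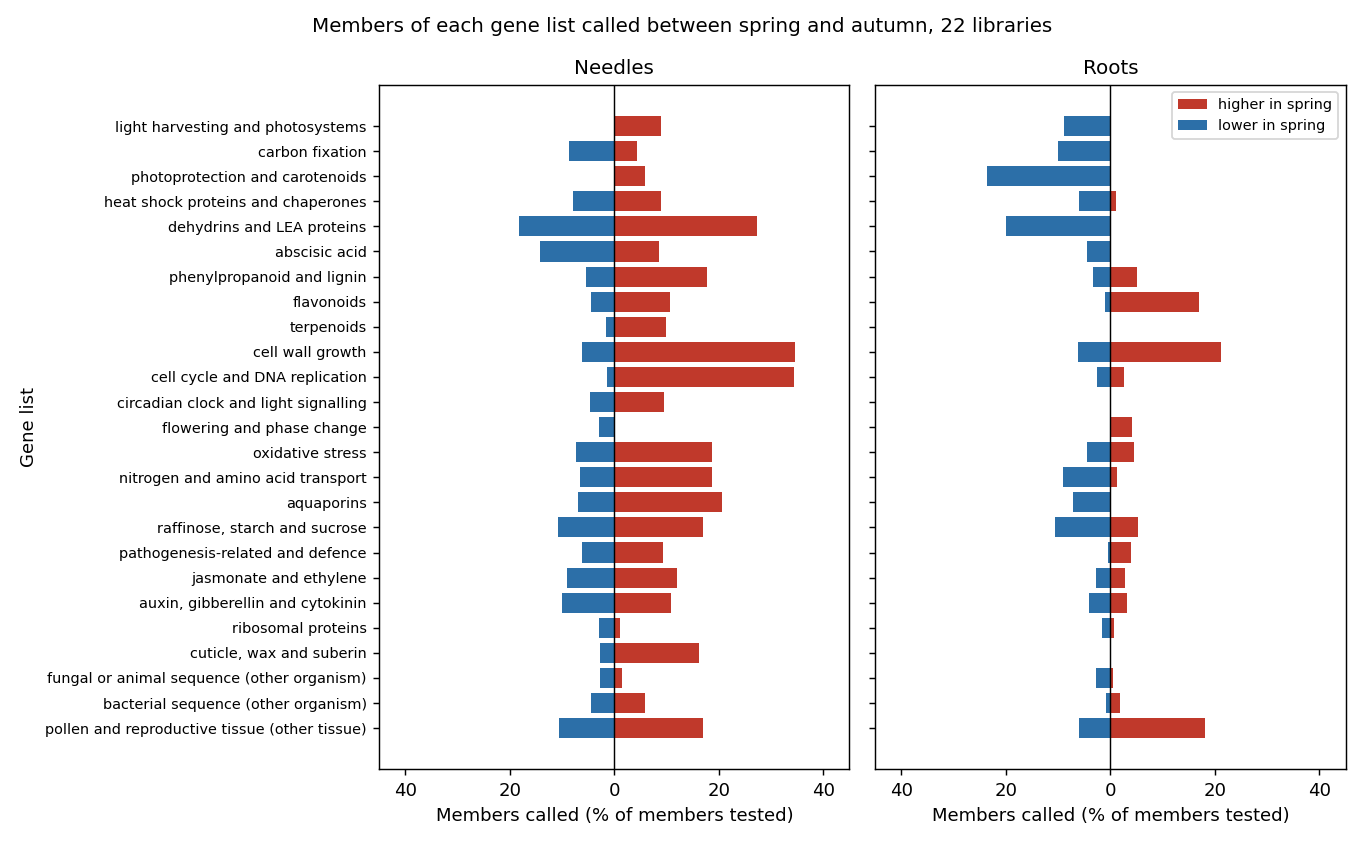
Percent of the tested members of each gene list (y axis, lists) called higher or lower in spring than in autumn (x axis, percent) in needles and in roots, from the fits without the 2 libraries that go against their organ label. In needles 70 of 204 cell cycle members were higher and 3 lower, and in roots 5 of 195 were higher and 5 lower.

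As labelled, 2225 of 19499 features passed the edgeR test for season in needles, 1429 higher and 796 lower in spring; without the 2 libraries 3142 of 20560 passed, 1807 higher and 1335 lower. With the tree as a block the number was 958 as labelled, 1312 without the 2 libraries and 4195 also without the needles of tree 1. DESeq2 called 3953 as labelled and 4744 without the 2 libraries. In the fit without the 2 libraries the number fell to as few as 1631 when another library was left out (spring needles of Ronda, replicate 1). Within Yunquera 825 features passed as labelled (487 higher, 338 lower) and 1731 without the 2 libraries (970 higher, 761 lower). Neither of the 2 is a Yunquera library, so this number changes only through the spread, filter and scaling that the fit shares over its groups. With the block the numbers were 133 (65 higher, 68 lower) and 677 (367 higher, 310 lower), and 3160 also without the needles of tree 1. DESeq2 called 2346 and 3586. The 1731 fell to 490 without autumn needles of Yunquera, replicate 3. Within Ronda 453 passed (253 higher, 200 lower) and 517 without the 2 libraries (248 higher, 269 lower), and 76 and 54 with the block (31 and 13 higher, 45 and 41 lower). Also without the needles of tree 1 the block gave 1302 (835 higher, 467 lower), and DESeq2 called 2034 as labelled and 1995 without the 2 libraries. The 517 fell to 93 without spring needles of Ronda, replicate 1. The dehydrin Gene_3530 fell at both sites, from 526 ± 218 to 0.868 ± 0.480 CPM at Yunquera (-9.22 ± 0.60, n = 3 and 3). At Ronda it went from 279 ± 105 to 0.831 ± 0.0955 CPM (-8.38 ± 0.70, n = 3 and 2). Among features tested at both sites, 171 were higher and 192 lower in spring at both, and 2 moved in opposite directions. Independent calls would give 11.7 and 9.96. The 2 comparisons share a fit and each feature's spread, so their calls are not independent and these numbers can be too low. The interaction of season and site called 0 of 19499 features in needles by edgeR (1377 at an unadjusted p under 0.05) and 178 by DESeq2. Without the 2 libraries edgeR called 0 of 20560 (1369 at an unadjusted p under 0.05) and DESeq2 220.

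The site comparison in needles asked how trees at the upper and lower limits differed in 1 season. In autumn, 9 of the 34 photoprotection members passed, all higher at Ronda. Their best hits are early light-induced proteins (ELIPs), chloroplast proteins made under excess light or cold. ELIPs were chosen for mention after their values were seen and were not tested as a group. ELIP1 (Gene_8363) stood at 1117 ± 364 CPM at Ronda and 10.1 ± 3.44 at Yunquera (SD, n = 3 and 3), with a log2 fold change of 6.79 ± 1.18. Gene_2963 stood at 4197 ± 1172 and 274 ± 39.5 CPM (3.94 ± 0.64). The list had 13 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.2e-08, adjusted p = 0.639 with an estimated correlation, and fry adjusted p = 0.0358. Of 83 raffinose, starch and sucrose members, 5 were higher and 3 lower (10 and 7 adjusted over the list alone, fry adjusted p = 0.00459). The starch synthase GBSS1 (Gene_39210) stood at 616 ± 102 CPM at Ronda and 75.4 ± 22.1 at Yunquera (3.03 ± 0.32), and TPS6 (Gene_11901, -1.79 ± 0.24) was lower at Ronda. PCK1 (Gene_33450, -3.66 ± 0.46), an enzyme of gluconeogenesis, was lower and the polyubiquitin UBI11 (Gene_75876, 4.81 ± 0.39) higher. The disease resistance protein SUMM2 (Gene_75900) was at least 222-fold higher, at 12.3 ± 5.78 CPM against no count at Yunquera. Adjusted p for these genes ran from 0.00392 to 0.0254 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

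As labelled, 36 features passed in autumn needles (21 higher and 15 lower at Ronda), and 352 without the 2 libraries (227 higher and 125 lower). Both are spring libraries and not in the groups compared. The number changes only through the spread, filter and scaling that the needle fit shares over its groups. By limma with the tree as a random term the numbers were 51 (19 higher and 32 lower) and 315 (184 and 131). DESeq2 called 1145 (611 and 534) and 2222 (1109 and 1113). The 36 fell to at most 3 when any of the 6 libraries was left out, and the 352 fell to 28 without autumn needles of Yunquera, replicate 3. No photoprotection member passed as labelled. Camera also placed cell wall growth (adjusted p = 4.69e-06, and adjusted p = 0.696 with an estimated correlation) and terpenoids (0.000936, and adjusted p = 0.704 with an estimated correlation) higher at Ronda. Fungal or animal sequence, a marker of other organisms, had a median of -2.95 (camera adjusted p = 5.83e-07, adjusted p = 0.864 with an estimated correlation). Filamentous fungal hits took 0.176 to 0.375% of counts in the Yunquera needles and 0.169 to 0.187% in those of Ronda. In spring needles edgeR called 0 features by site (2679 at an unadjusted p under 0.05) and DESeq2 821. Without the 2 libraries edgeR called 0 (2153 at an unadjusted p under 0.05) and DESeq2 622. Camera placed photoprotection higher at Ronda in spring too (median 0.43, adjusted p = 2.84e-05, adjusted p = 0.68 with an estimated correlation). Camera did so for the raffinose, starch and sucrose list (median 0.30, adjusted p = 0.00999, adjusted p = 0.288 with an estimated correlation, fry adjusted p = 0.00262). As labelled neither list passed by camera (adjusted p = 0.278, median -0.06 for photoprotection, and adjusted p = 0.172 for raffinose, starch and sucrose).

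The season comparison in roots put the same question to roots. Named genes that rose in spring roots included a wall enzyme and a chalcone synthase, and those that fell included GOLS2 and a dehydrin. XTH8 (Gene_3295), a wall-remodelling enzyme, rose from 19.8 ± 12.4 CPM in autumn (SD, n = 6) to 794 ± 677 CPM in spring (n = 5). Its log2 fold change was 5.50 ± 0.55. Chalcone synthase (CHS, Gene_21623), the entry to flavonoid synthesis, rose from 50.0 ± 92.5 to 349.8 ± 205 CPM (4.85 ± 0.78). GOLS2 (Gene_10499) makes the precursor of raffinose sugars. It fell from 108 ± 129.8 to 0.616 ± 0.229 CPM (-6.64 ± 0.54), which missed the threshold in the 24 libraries as labelled (-3.36, adjusted p = 0.122 by edgeR). The dehydrin Gene_5437 fell from 7392 ± 6825 to 309.5 ± 211 CPM (-4.78 ± 0.61).

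Further wall and phenolic genes rose in roots: FLA8 (Gene_18537, 2.31 ± 0.31), PMEU1 (Gene_26084, 5.78 ± 1.10), EXPB16 (Gene_21636, 13.67 ± 2.19), anthocyanidin reductase (Gene_64, 2.61 ± 0.34) and leucoanthocyanidin reductase (LAR, Gene_9250, 5.45 ± 0.67). PER27 (Gene_49668), a peroxidase, stood at 13.0 ± 17.5 CPM in spring and at no count in autumn, at least 425-fold higher. PER49 (Gene_17761) stood at 49.5 ± 39.2 CPM in autumn and no count in spring, at least 1828-fold lower. GOLS1 (ap_34676, 141 to 1505, -6.44 ± 0.50), AMY3 (ap_33391, 1 to 1827, -2.32 ± 0.37) and the protein phosphatase 2C Gene_15815 (-1.67 ± 0.23) fell, as did the nitrate transporter family member NPF6.4 (Gene_15893, -10.21 ± 1.15), the gibberellin-regulated GASA2 (Gene_33154, -4.66 ± 0.57) and the lipid-transfer protein CW18 (ap_4027, 1 to 671, -14.21 ± 2.38). WAT1-related transporters, a family whose members can share reads, held 3 of the largest falls (log2 fold change from -13.29 to -12.69). In spring roots these 3 stood at 0.0578 to 0.255 CPM and CW18 at 0.0561 CPM, with both organs scaled together. EXPB16 stood at 0.0418 CPM in autumn roots. Such levels are near the floor of 0.109 to 0.225 CPM in a single library, so the sizes of these changes are uncertain. Adjusted p for the genes of both paragraphs on roots ran from 0.000676 to 0.0297 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each moved the same way in all 5 trees with both libraries, which the naming rule required.

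Of 128 cell wall members in roots, 27 rose and 8 fell (58 and 15 adjusted over the list alone, median 1.19). The list had camera adjusted p = 5.43e-09, adjusted p = 0.613 with an estimated correlation, and fry adjusted p = 0.0182 (0.0882 with the block). Of 100 flavonoid members, 17 rose and 1 fell (33 and 4 adjusted over the list alone, median 0.92), with camera adjusted p = 8.59e-07, adjusted p = 0.68 with an estimated correlation, and fry adjusted p = 0.0476. Of 17 photoprotection members, 4 fell and 0 rose (9 and 1 adjusted over the list alone, median -2.37). Camera gave adjusted p = 0.000105, adjusted p = 0.192 with an estimated correlation, and fry adjusted p = 0.000642. As labelled, with the library labelled spring roots of Ronda, replicate 2, none of the 17 passed, the median was 0.34, and camera and fry, both toward lower, gave adjusted p = 0.175 and 0.656. With the block as labelled none passed either, the median was -1.11, and camera and fry gave adjusted p = 0.0430 and 0.556. Photosystem members had 4 of 45 lower and 0 higher (8 and 0 adjusted over the list alone, median -0.84, camera adjusted p = 2.84e-05, adjusted p = 0.696 with an estimated correlation). Their levels were low: the most abundant of the 4, Gene_4151, chosen after its values were seen, stood at 22.7 ± 15.5 CPM in autumn and 1.55 ± 2.31 in spring. Its fall was 0.651% of the needle level, under 1.58%, the 95th percentile of the 50 most abundant needle-specific features outside the photoprotection list, itself among them. As labelled none of 44 passed, and the median was 1.41 (camera adjusted p = 0.736), or -0.16 with the block (camera adjusted p = 0.626). Dehydrins and LEA proteins had 5 of 25 lower and 0 higher (7 and 0 adjusted over the list alone, median -0.08, and 0.20 as labelled, camera adjusted p = 0.0298, adjusted p = 0.835 with an estimated correlation). Defence members had 10 of 248 higher and 1 lower (2 and 1 adjusted over the list alone, median 0.88, camera adjusted p = 2.9e-06, adjusted p = 0.704 with an estimated correlation, fry adjusted p = 0.0626, and 0.0468 with RLE size factors). Pollen and reproductive tissue had 6 of 33 higher and 2 lower (9 and 2 adjusted over the list alone, median 1.94, camera adjusted p = 0.0105, adjusted p = 0.841 with an estimated correlation). Cell cycle members had 5 of 195 higher and 5 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.92).

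As labelled, 805 of 17899 features passed for season in roots (391 higher and 414 lower), and 1027 of 18538 without the 2 libraries (447 higher and 580 lower). With the block the numbers were 396 and 631 (266 higher and 365 lower), and DESeq2 called 2623 and 2752. The 1027 fell to as few as 358 when spring roots of Ronda, replicate 3, were left out. At Yunquera 63 features passed (40 higher and 23 lower, or 26 and 7 with the block). Without the 2 libraries 219 passed (116 and 103, down to 29 without spring roots of Yunquera, replicate 1). As both are Ronda libraries, this number too changes only through what the fit shares over its groups. At Ronda 4 passed (2 higher, 2 lower; 0 with the block), and 25 without the 2 libraries (15 and 10, down to 1 without autumn roots of Ronda, replicate 1 or 3). With the block and without the 2 libraries 29 passed there, 3 higher and 26 lower. GOLS2 (Gene_10499) fell at Yunquera from 198 ± 134 to 0.653 ± 0.258 CPM (-8.23 ± 0.70, n = 3 and 3, as-labelled adjusted p = 0.108 by edgeR). At Ronda GOLS2 fell from 18.3 ± 5.85 to 0.561 ± 0.257 CPM (-5.06 ± 0.74, n = 3 and 2). There the fit as labelled gave 1.50, and the block ended the call (adjusted p = 0.112 by edgeR). At Yunquera 8 of 100 flavonoid members passed, all higher, and 3 as labelled (32 adjusted over the list alone, median 1.69, camera adjusted p = 1.32e-10, adjusted p = 0.676 with an estimated correlation, fry adjusted p = 0.0578). With the block 16 passed there, all higher (fry adjusted p = 0.0297), and with RLE size factors fry gave 0.0476. At Ronda none was called (0 of 100, median 0.24, camera adjusted p = 0.151, and 0.000268 with the block).

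**Figure D4:**
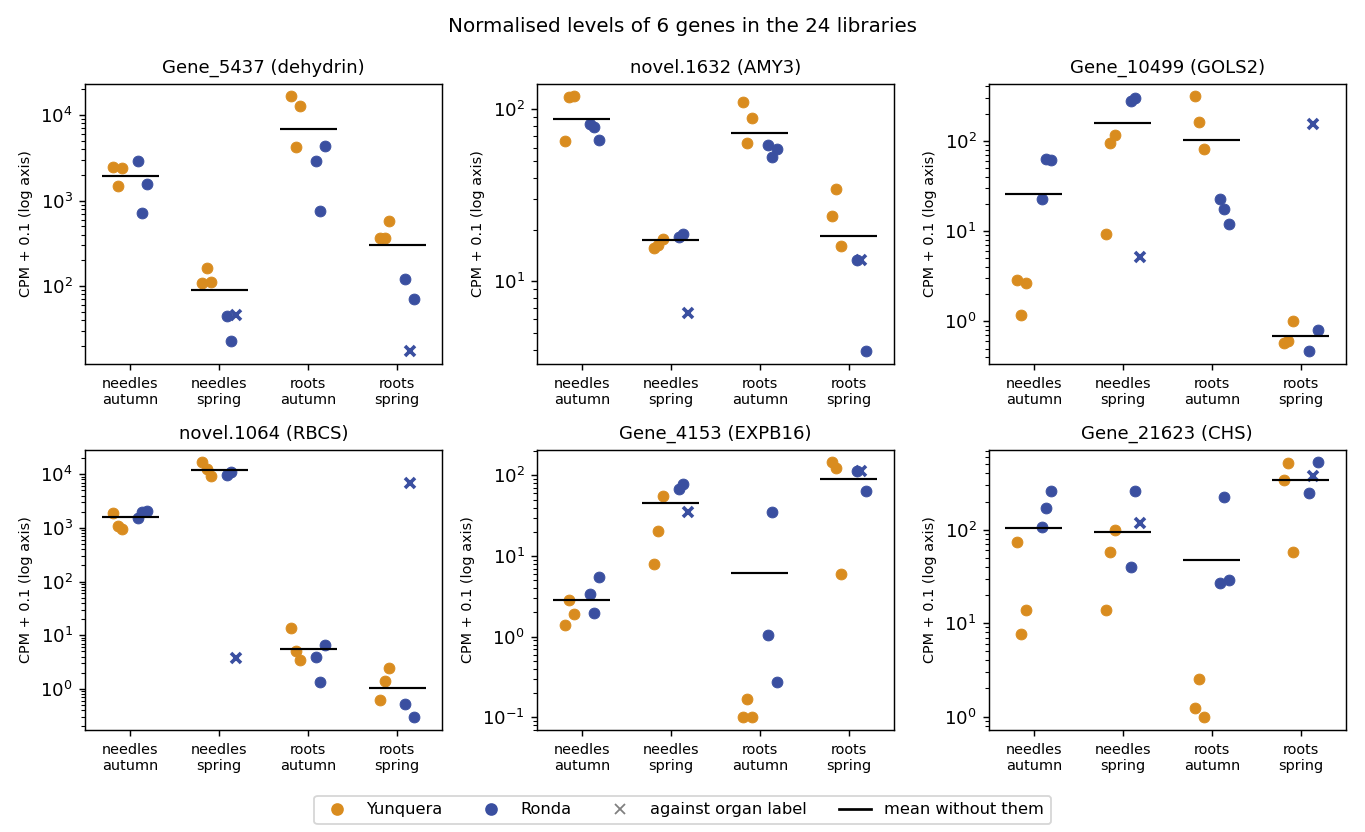
Levels of 6 genes (CPM plus 0.1, log axis) in needles and roots by season, with 1 point per library coloured by site, crosses for the 2 libraries that go against their organ label and lines for the mean without them. GOLS2 (Gene_10499) rises from 25.5 to 158 CPM on average in needles and falls from 101 to 0.594 CPM in roots, with all 24 libraries scaled together.

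By site, 6 features passed in autumn roots (5 higher and 1 lower at Ronda), the same numbers without the 2 libraries. Without the 2 libraries, edgeR called 0 when autumn roots of Ronda, replicate 1 or 2, or of Yunquera, replicate 1 or 2, were left out too. It called 1 when replicate 3 of Yunquera was left out and 5 when replicate 3 of Ronda was. By DESeq2 504 features passed as labelled, and 1747 had an unadjusted p under 0.05 by edgeR. The early nodulin-like protein Gene_15522 stood at 12.4 ± 7.90 CPM at Ronda and no count at Yunquera (SD, n = 3 and 3), at least 185-fold higher. The trihelix factor GT-3A (Gene_13639) stood at 45.2 ± 24.5 and 4.72 ± 0.938 CPM (3.26 ± 0.41). A homolog of ROOT HAIR DEFECTIVE 3 (Gene_85068) was lower at Ronda in autumn roots (1.45 ± 1.05 and 284 ± 87.9 CPM, -7.62 ± 0.81). In autumn needles it stood at 0.602 ± 0.272 and 126 ± 3.05 CPM (-7.68 ± 1.43). With the tree as a random block these genes missed the threshold: adjusted p by limma was 0.155 for Gene_15522, 0.173 for GT-3A, and 0.0517 in roots and 0.233 in needles for Gene_85068. Of 100 flavonoid members edgeR called none in autumn roots (19 higher and 1 lower at Ronda adjusted over the list alone, median 1.29, fry adjusted p = 0.128). Camera gave adjusted p = 4.02e-09, and adjusted p = 0.68 with an estimated correlation. For the interaction of season and site edgeR called no flavonoid member either (median -1.45, fry adjusted p = 0.214, camera adjusted p = 1.01e-09, adjusted p = 0.68 with an estimated correlation). In spring roots edgeR called 0 features by site (1113 at an unadjusted p under 0.05) and DESeq2 115. Without the 2 libraries edgeR called 0 (564 at an unadjusted p under 0.05) and DESeq2 88. The interaction of season and site in roots called 0 features by edgeR (844 at an unadjusted p under 0.05) and 65 by DESeq2. Without the 2 libraries edgeR called 0 (744 at an unadjusted p under 0.05) and DESeq2 77.

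The organ comparison gave the transcripts that set needles apart from roots. In spring, GAPB (Gene_37730), the chloroplast glyceraldehyde-3-phosphate dehydrogenase of the Calvin cycle, stood at 1625 ± 271 CPM in needles and no count in roots (SD, n = 5 and 5), at least 62624-fold higher. CFBP1 (Gene_5819), a chloroplast fructose bisphosphatase, stood at 997 ± 234 CPM and no count, at least 38405-fold higher. LHCA1 (Gene_2945, 8.87 ± 0.59), RBCS (ap_2297, 1 to 932, 14.02 ± 0.80) and a cytosolic glutamine synthetase (Gene_3187, 11.48 ± 0.65) were higher in needles. So were NCED1 (Gene_69197, 9.84 ± 0.75), which makes the precursor of abscisic acid, pinene synthase (Gene_8892, 8.81 ± 1.37) and the galactinol synthase GOLS1 (Gene_3136, 8.66 ± 2.02). Higher in roots were phenylalanine ammonia-lyase (PAL, Gene_5883, -1.80 ± 0.41), the pectinesterase PME53 (ap_19870, 1 to 1526, -5.66 ± 0.67), the glutathione transferase GSTF9 (Gene_5911, -2.94 ± 0.38), AHL22 (Gene_15926, -9.26 ± 0.71) and the cytochrome CYP71AU50 (Gene_3809, -5.94 ± 0.94). Adjusted p for these genes ran from 1.52e-09 to 0.00385 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each differed the same way in all 4 trees with both libraries, which the naming rule required. For GAPB, CFBP1, LHCA1 and RBCS the direction was also favoured by leaving out the 2 libraries, which was decided on photosynthesis transcripts.

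The 2 libraries were left out because their shares of photosystem and carbon fixation transcripts went against their label. That choice by itself favours higher levels of such transcripts in spring needles, so the spring values of these lists are no independent test. In spring 48 of 79 photosystem members were higher in needles and 0 lower (54 and 0 adjusted over the list alone, median 5.64, camera adjusted p = 3.03e-23, adjusted p = 0.288 with an estimated correlation). So were 27 of 34 photoprotection members, with 1 lower (29 and 1 adjusted over the list alone, median 6.64, camera adjusted p = 5.82e-18, adjusted p = 0.104 with an estimated correlation). Terpenoids had 25 of 64 higher and 1 lower (26 and 2 adjusted over the list alone, camera adjusted p = 0.00135, adjusted p = 0.798 with an estimated correlation). Cuticle, wax and suberin had 27 of 38 and 1 (27 and 1, camera adjusted p = 0.00236, adjusted p = 0.835 with an estimated correlation). Defence members had 21 of 268 higher and 32 lower in needles (18 and 22 adjusted over the list alone, median -0.60, camera adjusted p = 0.0064, adjusted p = 0.841 with an estimated correlation). Jasmonate and ethylene (20 of 156 higher, 26 lower, 21 and 26 adjusted over the list alone, median -0.32) had camera adjusted p = 0.0651, and 0.015 with the block. Fungal or animal sequence, a marker of other organisms, had 168 higher in needles and 23 lower (median 4.06, camera adjusted p = 0.205, fry adjusted p = 0.0400). With the block 54 were higher and 18 lower (fry adjusted p = 0.109). Of 398 features with filamentous fungal hits, 147 passed in spring (143 higher in needles) and 100 in autumn (95 higher). By share of counts, such hits took 0.369 and 0.257% in spring needles of Yunquera, replicates 1 and 2. They took 0.163 to 0.173% in the other spring needles and 0.165 to 0.183% in spring roots. The filter kept 400 such features in the needle fit and 43 in the root fit, which favours calls toward needles. The calls thus do not show more fungal RNA in needles in general. As labelled, 2002 of 20558 features passed in spring (1509 higher in needles, 493 lower), and 6094 of 21600 without the 2 libraries (4163 and 1931). As labelled the number ranged from 2 without spring needles of Ronda, replicate 2, to 4780 without the library labelled spring roots of Ronda, replicate 2. Each of the 12 libraries left out in turn moved it by over 1.5 times.

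In autumn 6280 features passed as labelled (3875 higher in needles, 2405 lower) and 6974 without the 2 libraries, which are both spring libraries (4070 and 2904). The guard cell anion channel SLAC1 (Gene_58545), which acts in stomatal closure, stood at 42.1 ± 28.7 CPM in needles and no count in roots (SD, n = 6 and 6), at least 1426-fold higher. The MADS-box gene AGL11 (Gene_67960) stood at 26.5 ± 6.60 CPM in roots and no count in needles, at least 1034-fold lower in needles. Lower in needles too were allene oxide cyclase (AOC, Gene_5970, -3.22 ± 0.29), an enzyme of jasmonate synthesis, and both histone H1 genes Gene_4386 (-1.74 ± 0.19) and Gene_3859 (-1.73 ± 0.19). Of 29 aquaporins, 3 were higher in needles and 13 lower (3 and 14 adjusted over the list alone, median -0.73, camera adjusted p = 0.0177, adjusted p = 0.574 with an estimated correlation). In spring 8 aquaporins were higher and 3 lower (median 0.08, camera adjusted p = 0.896, fry adjusted p = 0.182, and 0.0297 with the block). Of 209 cell cycle members 12 were higher and 42 lower (12 and 40 adjusted over the list alone, median -0.25 and mean 0.08). Camera pointed down (adjusted p = 0.00828, adjusted p = 0.798 with an estimated correlation). In spring the cell cycle list went the other way, with 50 higher in needles and 9 lower (median 0.49, camera adjusted p = 0.644). Fry gave adjusted p = 0.0378 there, and 0.0585 with the block. Adjusted p for the genes of this paragraph ran from 1.16e-07 to 0.00012 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

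The interaction of season and organ asked which season changes differed between needles and roots. RBCS (ap_2297, 1 to 932) was higher in spring in needles (1535 ± 453 to 11548 ± 2737 CPM, SD, n = 6 and 5) and lower in roots (5.75 ± 4.58 to 0.954 ± 0.880 CPM). The difference was 5.90 ± 0.69 on the log2 scale. The fall in roots was 0.0733% of the needle level, where the 50 most abundant needle-specific features outside the photoprotection list, RBCS among them, had a median of 0.258%. GOLS2 (Gene_10499) went from 24.9 ± 28.4 to 156 ± 119.9 CPM in needles and from 105 ± 126 to 0.589 ± 0.222 CPM in roots (10.51 ± 0.91). GOLS1 (ap_34676, 141 to 1505) went from 12.1 ± 13.1 to 77.1 ± 69.7 CPM and from 80.9 ± 73.2 to 0.567 ± 0.341 CPM (9.89 ± 0.82). AOC (Gene_5970) went from 13.2 ± 2.36 to 62.7 ± 33.7 CPM in needles and from 125 ± 33.8 to 146 ± 44.0 CPM in roots (2.00 ± 0.40). Adjusted p for these genes ran from 1.11e-05 to 0.00864 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. As labelled RBCS gave -0.83 (adjusted p = 0.929 by edgeR).

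Cell cycle members had 19 of 209 with a higher season change in needles and 0 lower (27 and 0 adjusted over the list alone, median 0.72, camera adjusted p = 7.59e-06, adjusted p = 0.68 with an estimated correlation, fry adjusted p = 0.0276, and 0.0564 with the block). Of 29 aquaporins 6 were higher and 0 lower (8 and 0 adjusted over the list alone, median 0.52, camera adjusted p = 0.00272, adjusted p = 0.332 with an estimated correlation, fry adjusted p = 0.00281). Photosystem members had 8 of 79 higher and 0 lower (20 and 1 adjusted over the list alone, median 1.01, camera adjusted p = 1.01e-05, adjusted p = 0.721 with an estimated correlation, fry adjusted p = 0.0637, and 0.042 with the block). As labelled none of 63 passed, and the median was -1.26 (camera adjusted p = 0.28). Nitrogen and amino acid transport had 12 of 96 higher and 1 lower (15 and 2 adjusted over the list alone, camera adjusted p = 0.0169, adjusted p = 0.798 with an estimated correlation, 0.0715 with the block, and 0.172 as labelled). Defence had 4 of 268 higher and 6 lower (4 and 6 adjusted over the list alone, median -0.88, camera adjusted p = 2.13e-05, adjusted p = 0.695 with an estimated correlation). As labelled, 253 of 20558 features passed (153 higher, 100 lower; 156 with the block), and 783 of 21600 without the 2 libraries (582 higher, 201 lower; 547 with the block, 428 higher and 119 lower). In the fit without the 2 libraries the number fell to as few as 387 when spring needles of Ronda, replicate 1, were left out. Among 17694 features tested in both organs, 173 were higher and 182 lower in spring in both, and 44 moved in opposite directions. Calls independent of each other and of a feature's level would give 39.8 and 41.9.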

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

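The tests of an exchange of the 2 libraries, of another of the 6 trees as the source of the needles of tree 1, and of needle RNA in the needle-specific photoprotection members, and every value without these libraries were chosen after the results were seen. The other tests of explanations were set before their results were seen.

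The library labelled spring needles of Ronda, replicate 3, held photosystem transcripts at 0.0370% of counts, against 3.00 to 5.64% in the other 11 needle libraries. The library labelled spring roots of Ronda, replicate 2, held 3.28%, against 0.0412 to 0.128% in the other 11 root libraries. RNA of the other organ mixed into a correctly labelled library is argued against: transcripts specific to the labelled organ stood at medians of 0.353% (527 features) and 1.05% (45 features) of their level in the other spring libraries of that organ. The on/off calls are consistent with an exchange of the 2 libraries for each other, since the lower of their shares of calls with the other library's tree was 91.5%. At which step an exchange could have happened is open, and no biological explanation was tested.

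Both needle libraries of tree 1 matched neither each other (61.7% of on/off calls) nor the roots of tree 1 (68.7 and 67.2%). A needle library that comes from another of the 6 trees is argued against, since the best mean share with another tree was 70.4%, under the 90% taken as a match. A mixture of 2 of the 6 trees that keeps the features of both above the level taken as on is argued against as well. In these libraries 34 and 24 on/off features were on, against up to 43 in libraries outside tree 1 and 42 to 57 in either of any 2 of the 6 trees. The test cannot decide on an uneven mixture, in which features of the minor tree can fall below that level. It has no benchmark for a mixture with a tree outside the 6. Both stay open. Needles from trees outside the 6 stay open and could not be tested here. No biological explanation was tested.

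Transcripts of the photoprotection and carotenoid list were lower in spring than in autumn roots without the 2 libraries (median log2 fold change -2.37 over 17 members). The 4 called were the ELIPs Gene_2963 and Gene_4036 and the carotenoid enzymes Z-ISO (Gene_8194) and BETA-OHASE 1 (Gene_11781). The member most abundant in roots, the ELIP Gene_228, went the other way without passing (426 CPM in autumn, 608 in spring, log2 fold change 0.51). As labelled, with the library labelled spring roots of Ronda, replicate 2, the median was 0.34 without the tree as a block and -1.11 with it. EdgeR called none in either. Needle RNA in the autumn root libraries is argued against as the whole cause, for members above a benchmark only. The excess of autumn over spring roots was 3.55% of the needle level in the median member. In 10 of 17 members, 3 of the 4 called among them, it was above 1.58%. That is the 95th percentile of the 50 most abundant other needle-specific features (median 0.258%), whose low level in autumn roots was part of their selection. Only 3 of the 17 members met the same rule, the called Gene_2963 among them (0.188%, chosen after its values were seen). For these 3 needle RNA stays open: 0 of them were above 1.58%, and their median excess of 0.123% was under that of the 50 features. With 3 members the test cannot decide. Dependence on 1 of the 11 other root libraries is argued against, since the median nearest to 0 was -1.62, without autumn roots of Ronda, replicate 3. A seasonal difference in roots stays open as a hypothesis and was not tested apart from the harvest year.

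The season change differed between needles and roots in 253 features as labelled, by the interaction test. The genes named here passed that test without the 2 libraries. Each value below is the difference of the season changes (needles minus roots, log2) in that fit, and levels are mean CPM with the SD (n = 6 in autumn and 5 in spring). RBCS (ap_2297) had 5.90, with 1535 ± 453 CPM in autumn needles and 11548 ± 2737 in spring needles. FTRC (Gene_5362) had 3.86, with 391 ± 93.5 and 605 ± 177 CPM in needles and 8.92 ± 3.85 and 0.944 ± 0.451 in roots. The excess of autumn over spring roots was 0.0733% of the needle level for RBCS and 1.60% for FTRC, against a median of 0.258% and a 95th percentile of 1.58% in the 50 needle-specific features, to which both belong. Needle RNA in autumn roots is thus not excluded for the root side of either. GOLS2 (Gene_10499) had 10.51, with 24.9 ± 28.4 and 156 ± 119.9 CPM in needles and 105 ± 126 and 0.589 ± 0.222 in roots, and GOLS1 (ap_34676) had 9.89. AOC (Gene_5970) had 2.00, with 13.2 ± 2.36 and 62.7 ± 33.7 CPM in needles. The histone H1 genes Gene_3859 and Gene_4386 had 1.68 and 1.43, with 656 ± 164 and 1486 ± 360 CPM, and 272 ± 74.5 and 638 ± 173 CPM, in needles. The thaumatin-like protein on ap_7456 had 3.25, with 332 ± 208 CPM in autumn roots and 29.7 ± 21.4 in spring roots, and ACO (Gene_60806) had 9.22, with 16.2 ± 18.9 and 0.247 ± 0.274. CW18 (ap_4027) had 15.41, with 1259 ± 1402 and 0.0561 ± 0.108 CPM in roots, and PME53 (ap_19870) had -6.35, with 4.02 ± 0.710 and 64.4 ± 83.0. PR-1C (Gene_18980) had -11.42, with 4.04 ± 3.41 CPM in autumn needles and 0.0736 ± 0.0469 in spring needles. In roots its means were 0.176 CPM in autumn and 2.90 in spring. Its levels in spring needles and autumn roots were near the floor of 0.109 to 0.225 CPM, so the size is uncertain. The WAT1-related Gene_20986 had 13.52, with 75.2 ± 78.9 CPM in autumn roots and no count in spring roots. CXE6 (Gene_68296) had 12.13 and no count in spring roots, and PER27 (Gene_49668) had -10.21 and no count in autumn roots. In autumn and spring needles CXE6 stood at 0.0705 and 0.0694 CPM and PER27 at 0.200 and 0.254 CPM. These needle levels are at or near the floor of 0.109 to 0.225 CPM, so a needle season change was barely measurable for either gene. The fitted values of Gene_20986, CXE6 and PER27 are no bounds. EXPB16 (Gene_21636) had -10.67, with 0.0418 ± 0.102 CPM in autumn roots and 315 ± 359.8 in spring roots. With the tree as a block, also without the 2 libraries, the adjusted p by edgeR was 0.0804 for CXE6, 0.0566 for PER27 and 0.0659 for EXPB16.

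Season in needles called 2225 genes as labelled, and 1 of 100 splits of the 12 libraries, the real one, called as many. The highest other called 35, and the highest of the other splits that part as many pairs called 1. Of the 32 splits that part all 6 trees, 1 called as many, and the highest other called 4. Season in roots called 805, and 1 of 100 splits called as many, with 2 in the highest other and 4 in the highest other that parts all 6 trees (1 of 32). Organ in autumn called 6280, in 1 of 100 splits, with 110 in the highest other, and season by organ called 253, in 1 of 100, with 26 in the highest other. Chance is excluded at a share under 0.05 for season in needles and in roots, and for organ in autumn over all 100 splits. Only 19 of the organ in autumn splits part all pairs, too few for such a share, and the highest other of them called 1. The splits for season by organ regroup the seasons within each organ, which also breaks up the season changes themselves. They cannot decide whether those changes differ between organs. Organ in spring called 2002, and 4 of 100 splits called as many, up to 2287. The split with 2287 moved both of the 2 libraries that go against their organ label to the other organ. The other 2 moved 1 of them and called 2265, the highest among the other splits that part as many pairs, and 2109. This points to a structure of the samples, although the share is under 0.05. For the comparisons of 3 against 3 the 10 splits are too few for a share under 0.05. Their real values and highest others were 825 and 14 (needles at Yunquera), 453 and 23 (needles at Ronda), 36 and 0 (site in needles in autumn), 63 and 0 (roots at Yunquera) and 6 and 0 (site in roots in autumn). For season in roots at Ronda they were 4 and 6 (2 of 10 as large). For 4 comparisons edgeR called 0, so 10 of 10 splits were as large. Site in needles in spring had 2679 features at an unadjusted p under 0.05 and 821 by DESeq2, and the highest other split called 1. For the other 3 the highest other called 0. Site in roots in spring had 1113 and 115 features by those counts, and the season by site interactions had 1377 and 178 in needles and 844 and 65 in roots.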

How the results depend on the processing

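The fits without the 2 libraries that go against their organ label, with the block or DESeq2 on top, and without the needles of tree 1 were chosen after the data were seen. The cause was not tested except where fewer libraries or features show it. Under RLE size factors and a minimum log2 fold change of 1, all 15 counts stayed within 1.5 times. DESeq2 called 3953 features for season in needles, 2346 at Yunquera, 2034 at Ronda, 1145 and 821 for site in autumn and spring needles, and 178 for their interaction. In roots DESeq2 called 2623, 1391, 860, 504, 115 and 65 for the same comparisons. It called 3719 for organ in spring and 1429 for season by organ. When the 2 libraries were left out, DESeq2 called 4744, 3586, 1995, 2222, 622 and 220 in needles, 2752, 1822, 861, 719, 88 and 77 in roots, 7340 for organ in spring and 2077 for season by organ. By edgeR, leaving them out gave 1731 for season in needles at Yunquera, 352 for site in autumn needles, 219 and 25 for season in roots at Yunquera and Ronda, 6094 for organ in spring and 783 for season by organ.

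The numbers in the labels were taken to give the same trees in both organs and seasons, so the tree was also used as a replicate block, which pairs the libraries. As labelled it gave 958, 133 and 76 for season in needles (both sites, Yunquera, Ronda), 396 and 33 for season in roots (both sites, Yunquera) and 156 for season by organ. For season in roots at Ronda it gave 0 by edgeR, with 1959 at an unadjusted p under 0.05. It moved no other count by over 1.5 times as labelled, apart from site in autumn roots, which called 1 with the tree as a random term. With the block and without the 2 libraries, season in needles gave 1312 (both sites) and 54 (Ronda), season in roots at Yunquera and Ronda 194 and 29, organ in spring 4991 and season by organ 547. At Ronda the needle calls then had 13 higher and 41 lower, against 248 and 269 without the block, and as labelled 31 and 45 against 253 and 200. Leaving out the needles of tree 1 as well gave 4195, 3160 and 1302 for season in needles (835 higher and 467 lower at Ronda, which turns the direction back), 11 for its interaction with site, 5243 for organ in spring and 552 for season by organ. With the tree as a random term and without the 2 libraries, site in needles gave 315 in autumn and 2 in spring. Site in autumn roots gave 0 by limma, with 2114 at an unadjusted p under 0.05.

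The stricter filter, which tests fewer features, gave 87 and 4 for site in autumn and spring needles, 150 for roots at Yunquera and 10 for site in autumn roots. No filter gave 7 for roots at Ronda and 157 for season by organ. With only the 6 libraries compared, 47 passed for needles at Ronda and 542 for site in autumn needles. That fit gave 0 by edgeR for roots at Ronda (1907 at an unadjusted p under 0.05) and for site in autumn roots (1615).

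Each library was also left out in turn, as labelled. Season in needles ran from 1105 to 3142, and moved by over 1.5 times without autumn needles of Yunquera, replicates 2 and 3, any of Ronda in autumn, or spring Yunquera replicate 2. At Yunquera it ran from 106 to 662 (all but spring replicate 1 moved it so), and at Ronda from 99 to 517 (autumn libraries and spring replicate 1). Site in autumn needles ran from 0 to 3, with all 6 libraries. Site in spring needles ran from 0 to 2 (Yunquera replicates 1 and 3, Ronda replicate 2), and the interaction from 0 to 1 (autumn Yunquera replicate 1). Season in roots ran from 180 to 1027 (autumn Yunquera replicate 3, autumn Ronda, spring Yunquera replicates 1 and 2, spring Ronda replicate 1). At Yunquera it ran from 7 to 55 (all but spring replicate 3), and at Ronda from 0 to 25 (all but spring replicate 1). Site in autumn roots ran from 0 to 5 (Yunquera, and Ronda replicate 1), site in spring roots from 0 to 3 (Ronda replicates 1 and 3) and the interaction from 0 to 1 (spring Ronda replicate 1). Organ in autumn ran from 4964 to 6019 with none, and organ in spring from 2 to 4780 with all 12. Season by organ ran from 50 to 422, with 18 of 24. The fits that gave 0 by edgeR had between 522 and 3151 features at an unadjusted p under 0.05.

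Of 2962 values over 141 pairs of a named gene and a comparison, 2398 kept their direction and side of the threshold, 450 were weaker, 106 stronger and 8 reversed. RBCS for season by organ was -0.83 as labelled, short of the threshold. It was 5.90 without the 2 libraries, 5.87 with the block, 5.92 by DESeq2, and 5.97 also without the needles of tree 1. With 1 library left out it ran from -1.19 to 5.55, the latter without spring roots of Ronda, replicate 2. GOLS2 (Gene_10499) for season in roots at Ronda was 1.50 as labelled, also short of the threshold. It was -5.06 without the 2 libraries and -5.02 by DESeq2, and ran from -5.06 (without that same library) to 2.09. Leaving out that library alone reversed both genes. A count of 3, the floor used here, stood for 0.109 to 0.225 CPM over the 24 libraries, which limits what can be told of features near it.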

Other observations

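The values without the 2 libraries and the genes named in this part were chosen after the values were seen. Among flavonoid genes, 4 that rose in spring roots are given here. Chalcone synthase (Gene_4403) went from 210.1 ± 335 to 1325 ± 739 CPM (SD, n = 6 and 5, log2 fold change 3.97), and LDOX (Gene_3800) from 11.1 ± 11.8 to 145 ± 122 CPM (4.70). Flavonoid 3',5'-hydroxylase (Gene_9511) went from 120.3 ± 197 to 642 ± 399.5 CPM (3.54), and flavonol synthase (Gene_7233) from 15.1 ± 19.2 to 102 ± 67.0 CPM (3.09). Each moved the same way in all 5 trees with both libraries, which leave out tree 5. Their adjusted p by edgeR was 0.0132, 0.0114, 0.0158 and 0.0383 in that order, and 0.00754, 0.00488, 0.00886 and 0.0421 with the tree as a block. As labelled, Gene_7233 missed the threshold (adjusted p by edgeR 0.0738). With all other libraries as labelled, Gene_3800 and Gene_9511 missed it without autumn roots of Ronda, replicate 3 (0.0570 and 0.0613), and Gene_9511 without spring roots of Yunquera, replicate 2 (0.0521).

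In autumn needles, 2 genes of the raffinose pathway were higher at Ronda without the 2 libraries. GOLS2 (Gene_10499) stood at 46.4 ± 21.1 CPM at Ronda and 2.02 ± 0.895 CPM at Yunquera, and RFS (ap_60466) at 136 ± 29.7 and 44.8 ± 3.03 CPM (SD, n = 3 and 3). Their adjusted p by edgeR was 0.0400 and 0.0266. As labelled both missed the threshold by edgeR (0.195 and 0.0865) and passed by DESeq2 (0.00194 and 0.000313). With the tree as a random term GOLS2 missed it without the 2 libraries too (adjusted p by limma 0.194), and RFS passed (0.0358).

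Best hits in yeasts took 1.15, 2.04 and 3.26% of counts in the autumn roots of Ronda. In those of Yunquera they took 3.83% in replicate 2 and 0.539 and 0.659% in the other 2. In spring roots they took 1.63% in Ronda, replicate 3, and 0.675 to 0.807% in the other 5 libraries labelled so. They took at most 0.937% in the 11 needle libraries that go with their label, and 1.08% in the library labelled spring needles of Ronda, replicate 3. The tables do not say whether these hits are sequences of yeast or conserved genes of the tree.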
